A study of Mus musculus with 23 samples.

How the data were processed

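Bulk RNA sequencing was deposited for 23 mouse libraries, 3 of heterozygous and 5 of knockout sorted alpha cells, 7 of knockout tumors and 8 of non-tumor pancreatic tissue. Per the labels' protocols, RNA was extracted with RNeasy and libraries were made with the TruSeq RNA kit. The submitters' processing notes name CASAVA 1.8, GSNAP and the mouse genome GRCm38, without their roles. The counter, gene annotation, filters and library totals are not given in the sources used here. The authors deposited 2 tables of RPKM values, 1 for alpha cells (28096 genes) and 1 for tissue (22412 genes). The file headers name no unit, and RPKM was read from the values: they are not whole, columns do not share a sum, and the worth of 1 read in the tissue table falls with gene length. Columns were matched to libraries by the identifiers in the labels, and no column of values was left without a library. A date stood in place of 25 symbols in the alpha cell table and 26 in the tissue table; the 25 were named from their gene identifiers. No symbol was given for 299 alpha cell entries, which kept their identifier.

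Of tissue values above 0, in 17573 genes, 100% were whole reads within 0.1 of a read once the step of each gene and library was found. This recovery returned 99.97% of 2973 simulated genes up to a factor common to all reads of a gene. The recovered totals were 7084676 to 15605157 reads, which are lower bounds because such a factor cannot be seen. The factor by which the authors scaled each library is not the inverse of that total: 1 read was worth 0.628 in tumor 1 relative to non-tumor library 1, although their totals were 13113945 and 14071432. The values can therefore be RPKM already normalised between libraries, or RPKM over totals that include reads outside the listed genes. These cannot be told apart here. Tissue fold changes on the deposited scale depend on that factor. Depth could not be recovered for the alpha cell table. Sums of RPKM there ran from 341401 to 658255. An exact 0 in that table is given as a gene listed at 0. Between libraries of a group, Pearson r of log2 values was 0.578 to 0.730 for heterozygous cells, 0.653 to 0.928 for knockout cells, 0.848 to 0.982 for non-tumor tissue and 0.885 to 0.969 for tumors.

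Values were tested on log2(RPKM + 1) with limma 3.58.1 (trend) in R 4.3.3, two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes entered with 1 RPKM or more in at least as many libraries as the smaller group held, 3 for alpha cells and 7 for tissue. A fold change on this scale understates the change of low genes. The tables were normalised separately and fitted separately, knockout against heterozygous cells and tumor against non-tumor tissue, without covariates. Where text speaks of centring, each library was set to the same median log2 value over the tested genes. Sex was read from Xist and Y-linked genes where a table listed them.

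The lists were alpha identity, beta identity, delta with PP and epsilon cells, acinar, ductal, endothelial, immune, fibroblast and mural, glial and nerve, adipocyte, proliferation, amino acid transporters, ATF4 amino acid response, mTORC1 pathway, unfolded protein response, neuroendocrine secretory, neuroendocrine transcription factors, PanNET and tumor suppressor genes, nutrient and hormone receptors, sterol synthesis, hypoxia and glycolysis, immediate early genes, interferon and antigen presentation, amino acid catabolism and urea cycle, ribosomal proteins, nuclear-encoded respiratory chain and mitochondrially encoded genes. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, where 3 or more members were measured. The estimated correlation was used on the deposited scale only. Shared changes were tested with a one-sided Fisher's exact test per direction. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work. Gene positions came from the GENCODE annotation of GRCm38.

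The design, lists and most alternative settings were fixed before the data were examined. The plan named 1 test for count tables and another for normalised values, and the latter was used. Named genes were Gcgr, Gcg, Ins1, Ins2, Sst, Slc38a5 and Mki67. Added to these per comparison were the 8 largest rises and 8 largest falls among called genes with groups apart and a mean of at least 1 RPKM, leaving out predicted genes and bare identifiers. The 2 members of lowest adjusted p of each list and the 8 largest shared changes completed the rule; many of the list members that met it are not named in the text, and 4 further genes that met it are not reported here.

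Alternatives were quantile normalization, median centring, array weights, pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 RPKM, a fold of at least 2, a replicate block, sex and acinar covariates, and each library left out in turn. Alternatives chosen after seeing the data were a covariate for, or restriction to, libraries with more or fewer genes detected, limma voom on the recovered reads with size factors or library totals, list tests on centred values, and the overlap of alpha cell calls as reported with centred tissue calls. The overlap with both comparisons centred was fixed beforehand.

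The fit was tested on simulated data with the real libraries' spread. For the alpha cell comparison (10718 genes) it recovered 0% of 67 genes changed by 1 log2 unit, 37.3% of 67 changed by 2 and 66.7% of 66 changed by 3, with 4 unchanged genes called. For the tissue comparison (10220 genes) it recovered 94.0%, 100% and 98.5%, with 15 unchanged genes called.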

Results

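RNA was sequenced in bulk from 23 mouse libraries in 4 groups, in a study of how loss of the glucagon receptor (GCGR) leads to amino acid-dependent neuroendocrine tumors of pancreatic alpha cells. Alpha cells, the glucagon-producing cells of the islet, were sorted by flow cytometry from mice heterozygous for the receptor gene (n = 3) and from homozygous knockouts (n = 5). A protocol text shared by all samples gives tamoxifen at 200 mg/kg for 5 days, with islets taken 14 to 21 days later. It was read as applying to the alpha cell mice only, since the tumor and non-tumor samples are labelled with treatment none. Tumors of knockout mice (n = 7) and non-tumor pancreatic tissue of knockout mice (n = 8) formed the other pair of groups. The alpha cell libraries held values above 0 for 13124 to 16579 genes each, and their depth is unknown. Heterozygous libraries 1 and 2 and knockout libraries 1 and 2 had 13124 to 13882 such genes, and the remaining 4 had 16123 to 16579. Over the listed genes, 7084676 to 14071432 reads were recovered for non-tumor libraries and 11088782 to 15605157 for tumors. Xist and Y-linked genes marked heterozygous library 3 as female and the other 7 alpha cell libraries as male. By the Y-linked genes, non-tumor libraries 2, 7 and 8 and tumor 2 were female. No pair of libraries of a group agreed within sampling noise in the tissue. The labels do not say which animals the libraries came from, so p-values measure the spread between these samples.

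Gcgr itself (chromosome 11, 120530699 to 120538986, GRCm38), the targeted gene, was listed at 0 RPKM in all 3 heterozygous libraries and in 4 of 5 knockout libraries. Knockout library 4 held 0.111 RPKM. In tissue Gcgr was at 0 in all 7 tumors and in 2 of 8 non-tumor libraries, and its highest non-tumor value was 0.135 RPKM. An annotated antisense gene, Gm11789, overlaps Gcgr, and its reads cannot be told from those of Gcgr without strand. The gene lay under the expression filter in both tables and was not tested. Its values do not check the labels of the alpha cell groups, since the heterozygous libraries were at 0 as well.

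Knockout alpha cells were compared with heterozygous alpha cells to find the transcripts that differ with genotype. Slc38a5, which encodes a sodium-coupled transporter of glutamine and other neutral amino acids, rose from 19.1 ± 10.4 RPKM (SD, n = 3) to 239.8 ± 52.9 RPKM (SD, n = 5) in the knockout. Its log2 fold change was 3.69 (SE 0.34, limma adjusted p = 0.000285). Dapl1, encoding death-associated protein-like 1, rose from 4.32 ± 2.69 to 199.8 ± 92.2 RPKM (log2 fold change 5.23, SE 0.48, adjusted p = 0.000285). Metallothionein 1 (Mt1), a metal-binding protein, fell from 37.1 ± 5.10 to 1.62 ± 2.28 RPKM, and the immediate early gene Ier2 fell from 31.1 ± 9.09 to 2.95 ± 2.54 RPKM. Glucagon (Gcg), the hormone of these cells, took 61.3 to 69.5% of the values of each library. It read 291660.1 ± 89646 RPKM in heterozygous and 354476 ± 63291 RPKM in knockout cells and did not pass the test (log2 fold change 0.31, SE 0.23, adjusted p = 0.663).

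Of 10718 genes tested, 17 rose and 11 fell in the knockout. Caveolin 1 (Cav1), the coat protein of caveolae, rose from 0.552 ± 0.440 to 27.2 ± 13.0 RPKM (log2 fold change 4.11, adjusted p = 0.00138). Cd2, a lymphocyte adhesion molecule, rose by 3.83 (adjusted p = 0.0138), with 0.484 ± 0.561 RPKM in heterozygous and 24.6 ± 20.01 RPKM in knockout cells. Secreted phosphoprotein 1 (Spp1) rose by 3.51, the neuropeptide precursor Vgf by 3.07 and apolipoprotein A-II (Apoa2) by 2.93, each with adjusted p = 0.00875. Mitochondrial creatine kinase Ckmt1 rose by 2.89 (adjusted p = 0.0157) and the meiotic cohesin Rec8 by 2.71 (adjusted p = 0.0351). Smaller rises were found for Peg10 (2.30), Ssr4 (1.77), Serping1 (1.76), selenoprotein P (Sepp1, 1.73) and the vitamin D-binding protein Gc (1.72). LOC100862198 and 2 rows with only a gene identifier also rose.

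Among the falls, the pancreatic protease gene Cpa1 changed by −4.40 (adjusted p = 0.0195), from 49.9 ± 48.0 to 0.781 ± 1.15 RPKM. Mt1 changed by −4.23 (adjusted p = 0.00954) and Ier2 by −3.16 (adjusted p = 0.0133). Arginase 1 (Arg1), which splits arginine into ornithine and urea, fell from 10.02 ± 0.477 to 0.902 ± 0.408 RPKM (log2 fold change −2.57, adjusted p = 0.0279). The transcription factors Jun and Egr1 changed by −1.99 (adjusted p = 0.0279) and −1.91 (adjusted p = 0.0445). The other falls were Ctxn2 (−2.86), Septin3 (−2.32), 1700066J24Rik (−3.93), Snord14a (−3.42) and Mir546 (−3.34). Snord14a lies within Rps13 and Mir546 within Ctdsp2, so reads of the host transcripts cannot be told from theirs. Insulin genes Ins1 (−0.83, adjusted p = 0.557) and Ins2 (−1.21, adjusted p = 0.342) did not pass, nor did Sst (−0.08, adjusted p = 0.981) or Mki67 (0.57, adjusted p = 0.726). Without a single library the count of 28 became 7 (heterozygous 2), 57 (heterozygous 3), 58 (heterozygous 1), 18 (knockout 3) or 16 (knockout 5). Other settings gave from 0 of 19527 genes with no expression filter (limma, 1443 at unadjusted p under 0.05) to 90 with array weights.

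**Figure D1:**
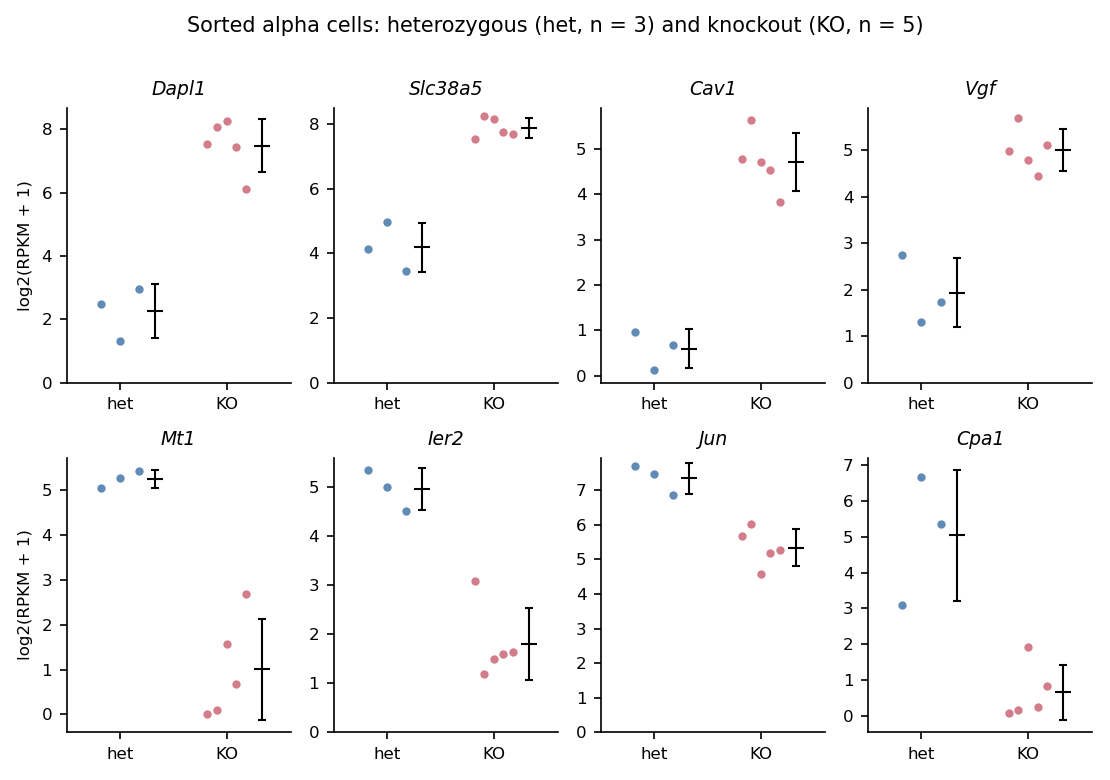
Expression of 8 genes in sorted alpha cells, as log2(RPKM + 1) on the vertical axis, for heterozygous (n = 3) and knockout (n = 5) libraries. Points are libraries and bars are the mean ± SD of the log2 values. Dapl1, Slc38a5, Cav1 and Vgf were higher in the knockout and Mt1, Ier2, Jun and Cpa1 lower; the log2 fold changes ran from −4.40 (Cpa1) to 5.23 (Dapl1).

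Of the gene lists, the immediate early genes, which cells switch on within minutes of stress such as tissue dissociation, stood lowest in p. Of 22 measured members, 3 fell (Ier2, Jun and Egr1), none rose and 19 did not pass. Adjusted over the list alone, 13 fell. The median log2 fold change was −1.54 and limma's camera test placed the list lower in the knockout (adjusted p = 1.67e-13). That call was lost at adjusted p = 0.162 with an estimated correlation and kept with fry (adjusted p = 0.0172). The mean log2 level of the list was 4.42 to 4.81 in heterozygous and 2.82 to 3.80 in knockout libraries.

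Acinar genes, which encode digestive enzymes of the exocrine pancreas, were lower in the knockout as well. Of 9 measured members 1 fell (Cpa1) and 7 fell adjusted over the list alone. Their median log2 fold change was −3.68 (camera adjusted p = 2.79e-05, and adjusted p = 0.434 with an estimated correlation), and Cela2a read −4.19 (adjusted p = 0.214). The heterozygous libraries differed among themselves. Acinar genes reached 0.270% of their level in non-tumor tissue in heterozygous library 2, 0.0975% in library 3 and 0.0004% in library 1, against 0.0001 to 0.0033% in the knockout, where levels across the 2 tables come from separate normalisations. Carry-over at that level would give 83.9% of the fall of Cpa1, 0.343% of that of Mt1 and 0.039% of that of Arg1. The level was itself read from 19 acinar genes and Cpa1 belongs to that list, so the value for Cpa1 is not an independent test.

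Genes of the nuclear-encoded respiratory chain lay slightly higher in the knockout by their median, without any single gene called. None of 77 members passed, 1 rose adjusted over the list alone, and the median was 0.34 (camera adjusted p = 0.000696; adjusted p = 0.325 with an estimated correlation). Its lowest member in p was Ndufa1 (1.46, adjusted p = 0.105). The unfolded protein response list, which holds chaperones of the endoplasmic reticulum, had none of 23 members past the test over all genes or over the list alone. Its median was 0.35 (camera adjusted p = 0.0437, and adjusted p = 0.301 with an estimated correlation), with Manf at 0.90 (adjusted p = 0.376). Fry called the unfolded protein response (adjusted p = 0.00915) and the immediate early list, and no other alpha cell list. The ductal list had 1 of 7 members up (Spp1), the same 1 adjusted over the list alone, and a median of 0.68 (camera adjusted p = 0.0115; adjusted p = 0.301 with an estimated correlation). The list of delta, PP and epsilon cell genes had none of 4 past the test and 2 up adjusted over the list alone, with a median of 0.72 (camera adjusted p = 0.0437; adjusted p = 0.541 with an estimated correlation). Pyy read 0.96 (adjusted p = 0.283) and Rbp4 1.19 (adjusted p = 0.290). Neuroendocrine transcription factors had none of 14 past the test over all genes or the list alone and a median of −0.32 (camera adjusted p = 0.0377; adjusted p = 0.434 with an estimated correlation). Foxa2 read −1.24 (adjusted p = 0.311). With the acinar level as a covariate, only the immediate early list of the 6 others kept its call (adjusted p = 0.000124), and without heterozygous library 2 only that list and the acinar list did.

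**Figure D2:**
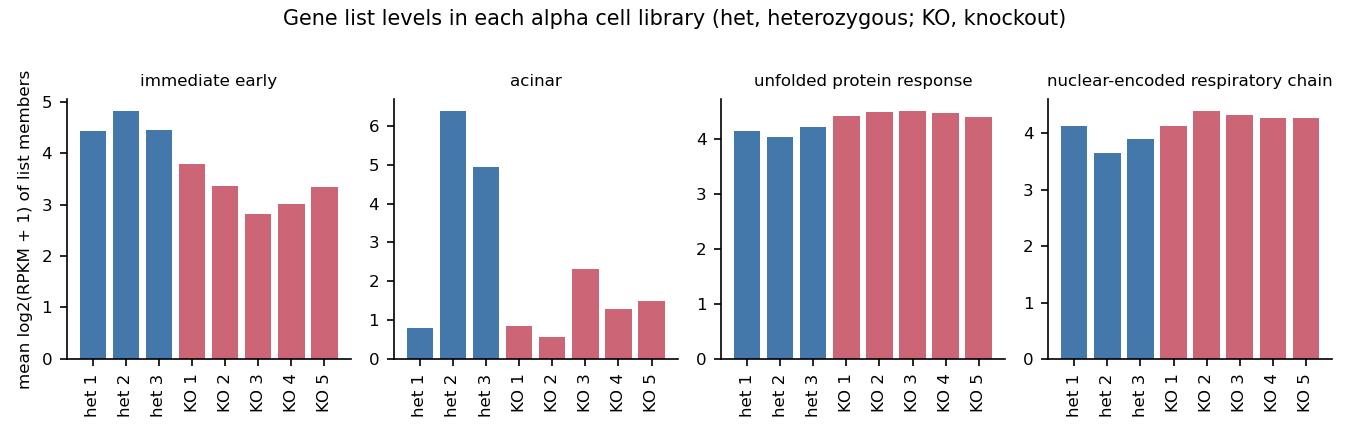
Mean log2(RPKM + 1) level of 4 gene lists in each of the 8 alpha cell libraries (bars start at 0). The immediate early list lay at 4.42 to 4.81 in the 3 heterozygous libraries and 2.82 to 3.80 in the 5 knockout libraries, and the acinar list was highest in heterozygous libraries 2 (6.38) and 3 (4.93).

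The other 16 lists tested in alpha cells gave no camera call. Amino acid transporters had 1 of 17 members up, Slc38a5, with 1 up and 1 down adjusted over the list alone and a median of −0.25 (camera adjusted p = 0.421); the arginine and lysine transporter Slc7a2 read −1.12 (adjusted p = 0.187). Amino acid catabolism and urea cycle genes had 1 of 16 down, Arg1, which was also the 1 found adjusted over the list alone (median −0.16, camera adjusted p = 0.421). The ATF4 amino acid response had none of 15 past either adjustment (median −0.10, camera adjusted p = 0.634), with Ddit4 at −2.27 (adjusted p = 0.477). The mTORC1 pathway, which senses amino acids, had none of 26 (median 0.14, camera adjusted p = 0.413). Neuroendocrine secretory genes had 1 of 26 up, Vgf, with 4 up and 3 down adjusted over the list alone. Their median was −0.06 while the mean (0.09) and the camera test (adjusted p = 0.628) lay upward. PanNET and tumor suppressor genes had none of 21 past the test and 2 up adjusted over the list alone (median 0.16, camera adjusted p = 0.413). Cdkn2c, an inhibitor of CDK4 and CDK6, read 1.84 (adjusted p = 0.220) and Phlda3 1.63 (adjusted p = 0.254).

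Alpha identity genes had none of 13 past either adjustment (median −0.40, camera adjusted p = 0.518) and beta identity genes none of 8 (median −0.22, camera adjusted p = 0.628). Proliferation genes had none of 10 (median 0.08, camera adjusted p = 0.680) and nutrient and hormone receptors none of 13 (median −0.29, camera adjusted p = 0.628). Interferon and antigen presentation genes had none of 13 (median 0.33, camera adjusted p = 0.413) and ribosomal proteins none of 54 (median 0.06, camera adjusted p = 0.689). Immune genes had none of 9 (median 1.10, camera adjusted p = 0.288); their mean log2 level was 4.01 in knockout library 5 and 0.556 to 1.97 in the other 7. Sterol synthesis genes had none of 14 past the test, 1 up and 2 down adjusted over the list alone, a median of 0.17, a mean of −0.11 and a downward camera test (adjusted p = 0.996). Hypoxia and glycolysis genes had none of 16 past either adjustment, a median of 0.15, a mean of −0.02 and a downward test (adjusted p = 0.996). Fibroblast and mural genes had none of 3 past either adjustment, a median of 0.07, a mean of −0.25 and a downward test (adjusted p = 0.996). Glial and adipocyte genes had 1 measured member each, Mbp and Pnpla2, neither past the test. No endothelial or mitochondrially encoded gene passed the expression filter.

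Tumors were compared with non-tumor pancreatic tissue of knockout mice to describe the tumor transcriptome. Glucagon was the leading transcript of every tumor, at 172409 ± 22361 RPKM (SD, n = 7) against 189 ± 139 RPKM (SD, n = 8), and took 27.8 to 46.8% of tumor values. Transthyretin (Ttr), abundant in alpha cells, read 17747 ± 5319 against 34.9 ± 19.9 RPKM. Acinar digestive enzymes fell, among them the elastase gene Cela2a, from 72946 ± 5254 to 2249 ± 2034 RPKM. The acinar list took 72.1 to 81.2% of the values in non-tumor tissue and 1.10 to 28.0% in tumors.

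On the deposited scale 9271 of 10220 genes rose and 376 fell in tumors (limma adjusted p under 0.05), and the median gene changed by 1.46 log2 units. Centring each library on its median gene moved fold changes by 1.54 and gave 2927 rises and 3746 falls. Fold changes are therefore given on the deposited scale and then relative to that shift. The pseudocount of 1 RPKM compresses the changes of low genes. With pseudocounts of 0.1 and 0.01 the median gene changed by 2.00 and 2.09. A low gene can therefore read below the shift through the pseudocount. Gcg rose by 10.18 (adjusted p = 1.54e-12), or 8.64 relative to the shift. The other largest rises were Ttr (9.07, 7.53 relative to the shift), the amino acid transporter partner Tmem27 (8.82, 7.28), elongation factor Eef1a2 (7.63, 6.09), Vgf (7.51, 5.97), Gc (7.41, 5.87), peptide YY (Pyy; 7.38, 5.84) and Dapl1 (7.36, 5.82). Slc38a5 rose from 40.9 ± 10.7 to 772 ± 440 RPKM (4.03, adjusted p = 5.97e-10; relative to the shift 2.49, adjusted p = 3.77e-06).

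The largest falls were in pancreatic enzyme and secretory genes. Cela2a changed by −5.83 (−7.37 relative to the shift), Cela1 by −5.69 (−7.23), the protease Ctrc by −5.53 (−7.07) and phospholipase Pla2g1b by −5.50 (−7.04). Try4 changed by −5.14 (−6.68), Ctrl by −4.98 (−6.52), trefoil factor Tff2 by −4.92 (−6.45) and the lipase Pnlip by −4.91 (−6.44). Insulin 2 read 864 ± 1486 RPKM in tumors and 2134 ± 1878 RPKM in non-tumor tissue, a change of −2.64 (adjusted p = 0.0257; −4.18 relative to the shift, adjusted p = 0.00233). Ins1 changed by −2.62 (adjusted p = 0.0233; −4.16 relative to the shift, adjusted p = 0.00191). On the deposited scale neither insulin gene passed without tumor 3 (Ins2 −1.78, Ins1 −1.89) or without tumor 1 (Ins2 −2.21, Ins1 −2.19). Reads of Ins1 and Ins2, and of the trypsin, elastase and amylase families, come from similar sequences and could be split between members. Somatostatin (Sst) rose by 2.59 (adjusted p = 0.0146) but not relative to the shift (1.05, adjusted p = 0.332). The proliferation marker Mki67 likewise rose by 1.40 (adjusted p = 0.000235) and read −0.14 relative to the shift (adjusted p = 0.639). At 0.959 RPKM in non-tumor tissue and 4.07 RPKM in tumors, Mki67 is a low gene, and the pseudocount may enter that reading.

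**Figure D3:**
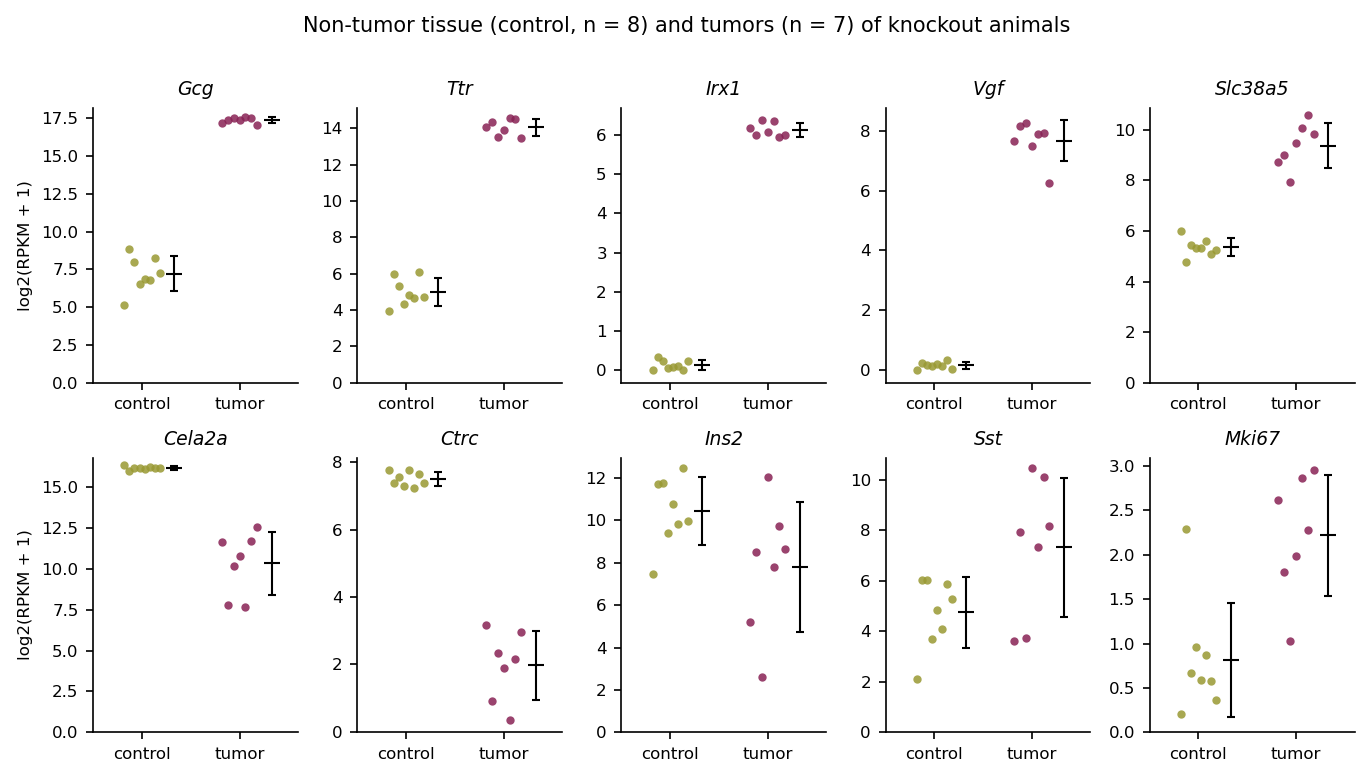
Expression of 10 genes in non-tumor tissue (n = 8) and tumors (n = 7), as log2(RPKM + 1) on the vertical axis on the deposited scale. Points are libraries and bars are the mean ± SD of the log2 values. Gcg, Ttr, Irx1, Vgf and Slc38a5 were higher in tumors and Cela2a and Ctrc lower on both scales, while the rises of Sst (2.59) and Mki67 (1.40) did not pass relative to the shift (1.05 and −0.14).

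Alpha identity genes rose together. Of 12 members 11 rose and none fell on the deposited scale, and the same number rose adjusted over the list alone; relative to the shift 11 rose and 1 fell. Irx1 and Irx2, alpha cell homeobox factors, rose by 6.01 and 5.58 (4.47 and 4.04 relative to the shift). The list median was 5.07 (3.53 relative to the shift), with a camera adjusted p = 0.0119, and adjusted p = 0.615 with an estimated correlation. Neuroendocrine secretory genes had 24 of 25 up (24 adjusted over the list alone; 23 up and 1 down relative to the shift). Their median was 5.04 (3.50), and Vgf and the peptide-amidating enzyme Pam (5.83, 4.29) had the lowest adjusted p of the list (camera adjusted p = 0.00342; adjusted p = 0.682 with an estimated correlation). Neuroendocrine transcription factors had 13 of 15 up (13 adjusted over the list alone; 12 up and 2 down relative to the shift), with Isl1 at 5.20 (3.66) and Fev at 3.73 (2.19). Their median was 3.61 (camera adjusted p = 0.0230; adjusted p = 0.682 with an estimated correlation). On centred values all 3 lists kept their upward call, at adjusted p = 1.15e-07, 1.24e-12 and 8.07e-07.

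Delta, PP and epsilon cell genes had 5 of 6 up, also adjusted over the list alone, and 3 up and 2 down relative to the shift. Rbp4 rose by 6.77 (5.23) and Pyy by 7.38 (5.84); the median was 4.24 while the camera test lay downward (adjusted p = 0.350) and, on centred values, upward (adjusted p = 0.326). Of 11 beta identity genes 1 rose and 5 fell, the same numbers adjusted over the list alone, and 1 rose and 9 fell relative to the shift. The zinc transporter Slc30a8, also a gene of alpha cells, rose by 5.36 (3.82) and Ero1lb changed by −0.93 (−2.47). The beta list median was −0.93 (camera adjusted p = 1.88e-12; adjusted p = 0.0508 with an estimated correlation; adjusted p = 0.0604 on centred values).

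All 24 acinar genes fell on both scales and adjusted over the list alone, with a median of −4.24 (−5.78 relative to the shift). The camera adjusted p was 4.52e-69, and adjusted p = 0.0195 with an estimated correlation. Amylase Amy2a5 changed by −1.76 (−3.30). Ductal genes went both ways, with 5 of 11 up and 4 down (4 and 4 adjusted over the list alone) and 2 up and 8 down relative to the shift. Keratin 7 (Krt7) rose by 4.59 (3.05), Epcam by 3.01 (1.47) and Tff2 fell. Their median was 0.48 while the mean was −0.12 and the camera test lay downward (adjusted p = 6.30e-09; adjusted p = 0.0422 with an estimated correlation; adjusted p = 0.0655 on centred values).

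All 13 endothelial genes rose, also adjusted over the list alone, and relative to the shift none rose and 5 fell (median 1.08, −0.46 relative to the shift). Esam read 1.33 (−0.21) and Plvap 1.42 (−0.12). Of 11 immune genes 7 rose, also adjusted over the list alone, and none changed relative to the shift (median 1.45, −0.09), with C1qa at 1.95 (0.41) and Cd68 at 1.81 (0.27). Fibroblast and mural genes had 9 of 14 up (8 adjusted over the list alone) and 3 up and 3 down relative to the shift (median 1.44, −0.10), with the matrix genes Mgp at 3.55 (2.01) and Postn at 2.65 (1.11). The camera test placed all 3 lists lower than other genes (adjusted p = 0.0282, 0.00712 and 0.00222). Those calls were lost at adjusted p = 0.709, 0.682 and 0.682 with an estimated correlation, and at adjusted p = 0.241, 0.847 and 0.940 on centred values. The 1 measured glial gene, Mbp, and 1 of 2 adipocyte genes, Pnpla2, rose on the deposited scale, also adjusted over the list alone. Relative to the shift Mbp and both adipocyte genes, Pnpla2 and Fabp4, fell.

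Of 23 amino acid transporters 18 rose and 4 fell, also adjusted over the list alone, and 9 rose and 12 fell relative to the shift. The system A transporter Slc38a4 rose by 5.12 (3.58), the neutral amino acid transporter Slc6a17 by 3.44 (1.91) and Slc38a5 by 4.03 (2.49). The transporter list median was 1.25 (−0.29), with the mean also above 0 and the camera test downward (adjusted p = 0.0179; adjusted p = 0.682 with an estimated correlation; adjusted p = 0.940 on centred values). The ATF4 amino acid response had 6 of 20 up and 11 down (6 and 10 adjusted over the list alone), and 1 up and 16 down relative to the shift. Sesn2, an inhibitor of mTORC1, rose by 4.00 (2.47) and the serine synthesis enzyme Phgdh changed by −2.62 (−4.16). Its median was −0.30 (camera adjusted p = 5.25e-19; adjusted p = 0.0241 with an estimated correlation). Amino acid catabolism and urea cycle genes had 8 of 19 up and 8 down, also adjusted over the list alone, and 3 up and 12 down relative to the shift. Tyrosine aminotransferase (Tat) rose by 3.42 (1.88). Their median (0.24) and mean (0.34) lay above 0 and the camera test downward (adjusted p = 2.10e-12; adjusted p = 0.0217 with an estimated correlation). On centred values the last 2 lists kept their downward calls (adjusted p = 2.93e-05 and 0.00668).

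The mTORC1 pathway had 23 of 26 up and 1 down, also adjusted over the list alone, and 8 up and 9 down relative to the shift. Gatsl2, of the CASTOR family of arginine sensors, rose by 4.52 (2.98), the list median was 1.45 (−0.09) and the camera test made no call (adjusted p = 0.617). All 22 PanNET and tumor suppressor genes rose, also adjusted over the list alone, and 12 rose and 1 fell relative to the shift. Cyclin D2 (Ccnd2) rose by 4.56 (3.02) and the cell cycle inhibitor Cdkn1a by 3.07 (1.53), with a list median of 1.86 (0.32; camera adjusted p = 0.154, adjusted p = 0.754 with an estimated correlation, and adjusted p = 0.00531 on centred values). Nutrient and hormone receptors had 12 of 14 up and 2 down, also adjusted over the list alone, and 9 up and 4 down relative to the shift. The fatty acid receptor Ffar4 rose by 3.60 (2.06) and the lipid receptor Gpr119 by 4.90 (3.36), with a list median of 2.73 (1.19; camera adjusted p = 0.865, adjusted p = 0.894 with an estimated correlation, and adjusted p = 0.0374 on centred values). All 23 proliferation genes rose, also adjusted over the list alone, and 2 rose and 5 fell relative to the shift. E2f1 rose by 2.27 (0.73) and Ccne1 by 1.12, but Ccne1 read −0.42 relative to the shift. Ccne1 lay at 0.318 RPKM in non-tumor tissue and 1.83 RPKM in tumors, so its sign relative to the shift may come from the pseudocount. Counts of low members relative to the shift have the same limit. The list median was 1.36 (−0.18) and the test downward (camera adjusted p = 0.350).

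The unfolded protein response had 18 of 23 up and 2 down, also adjusted over the list alone, and 9 up and 10 down relative to the shift. The sensor kinase Ern1 rose by 2.52 (0.98) and the disulfide isomerase Pdia3 by 3.54 (2.00). Its median was 1.66 (0.12 relative to the shift, where the mean was −0.24) and the camera test lay downward (adjusted p = 0.0282; adjusted p = 0.709 with an estimated correlation; adjusted p = 0.932 on centred values). Sterol synthesis genes had 13 of 15 up, also adjusted over the list alone, and 3 up and 10 down relative to the shift, with Sqle at 2.21 (0.67), Mvk at 1.78 (0.24) and a median of 1.20 (camera adjusted p = 0.554). Hypoxia and glycolysis genes had 14 of 15 up, also adjusted over the list alone, and 4 up and 6 down relative to the shift, with Vegfa at 3.05 (1.51), P4ha1 at 2.44 (0.90) and a median of 1.36 (camera adjusted p = 0.554). Both tests lay downward. Immediate early genes had 15 of 18 up, also adjusted over the list alone, and 2 up and 5 down relative to the shift (median 1.36, −0.18), with Btg2 at 2.16 (0.62). Interferon and antigen presentation genes had 18 of 19 up, also adjusted over the list alone, and 3 up and 2 down relative to the shift, with Usp18 at 2.56 (1.02) and H2-K1 at 2.88 (1.34). Their median was 1.38 (−0.16 relative to the shift, where the mean was 0.06). The camera test placed the last 2 lists lower than other genes (adjusted p = 0.0259 and 0.0317; adjusted p = 0.709 for both with an estimated correlation; adjusted p = 0.750 and 0.793 on centred values).

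Ribosomal protein genes had 22 of 27 up, also adjusted over the list alone, and none up and 22 down relative to the shift. Rpl7 read 1.19 (−0.35) and Rpl19 1.33 (−0.21). Their median was 0.92 (−0.62; camera adjusted p = 0.0144, downward; adjusted p = 0.709 with an estimated correlation; adjusted p = 0.000531 on centred values). Nuclear-encoded respiratory chain genes had 66 of 69 up, also adjusted over the list alone, and 7 up and 32 down relative to the shift, with Ndufa1 at 2.54 (1.00). Their median was 1.28 (−0.26), and the camera test was upward (adjusted p = 0.436; adjusted p = 0.867 with an estimated correlation) and downward on centred values (adjusted p = 0.0394). Mitochondrially encoded genes had 2 of 10 up, mt-Nd5 (1.77, 0.23) and mt-Nd6 (1.81, 0.27), also adjusted over the list alone, and none up and 7 down relative to the shift. Their median was 0.40 (−1.14) and the camera test lay downward (adjusted p = 0.000165; adjusted p = 0.615 with an estimated correlation; adjusted p = 0.170 on centred values).

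**Figure D4:**
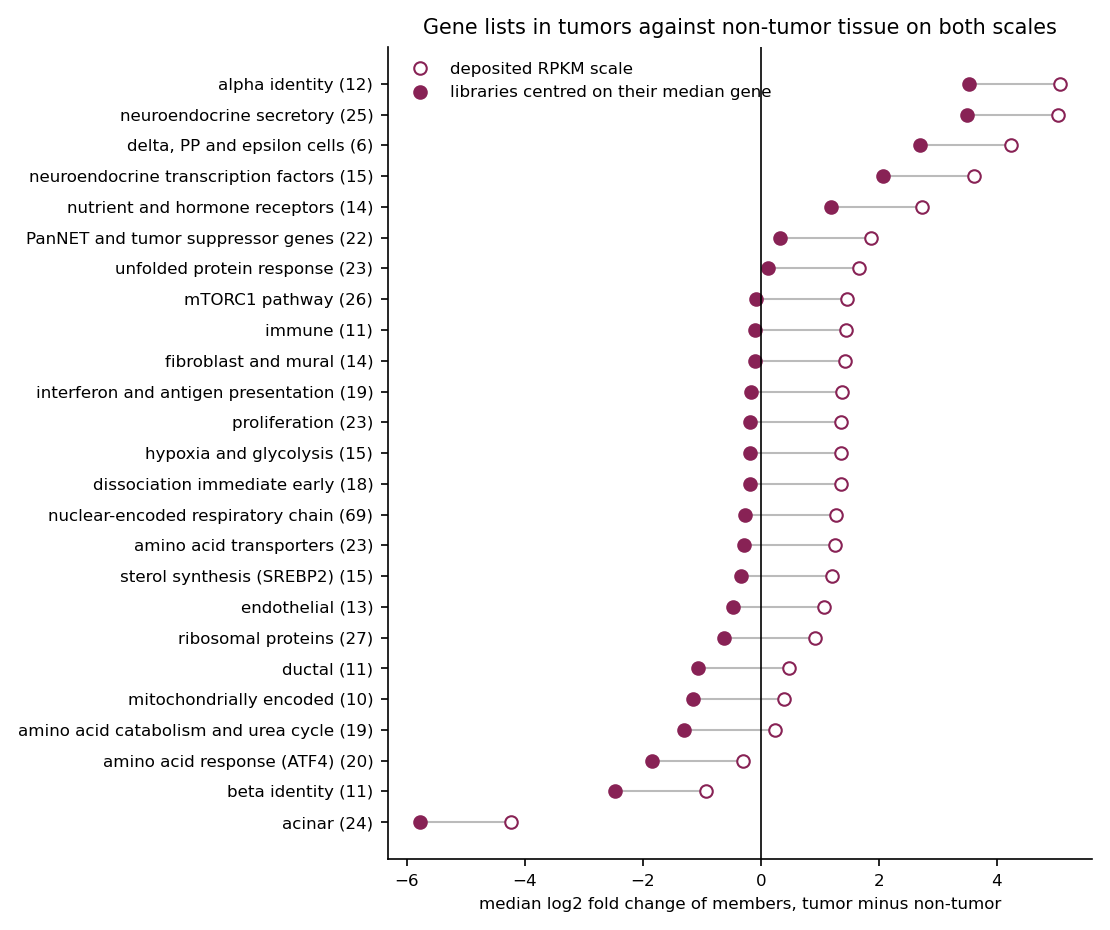
Median log2 fold change of each gene list in tumors minus non-tumor tissue, with the number of measured members in brackets. Open circles are on the deposited scale and filled circles after centring each library on its median gene; alpha identity (5.07 and 3.53) and acinar genes (−4.24 and −5.78) lay at the ends on both scales.

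The genes called in sorted knockout alpha cells were looked up in the tumor comparison. That comparison sets tumors of alpha cells against mostly acinar tissue, so genes of alpha cells rise in it whatever the genotype: 11 of 12 alpha identity genes rose relative to the shift, and none of 13 was called in knockout alpha cells. Gc, for example, read 49.8 RPKM in heterozygous alpha cells, 1.21 RPKM in non-tumor tissue and 390 RPKM in tumors. By direction alone, a shared rise like that of Gc therefore cannot be told from alpha cell content. Slc38a5 read 19.1 RPKM in heterozygous alpha cells, 40.9 RPKM in non-tumor tissue and 772 RPKM in tumors, which argues against such content alone for Slc38a5. Rec8 (0.610, 1.02 and 27.5 RPKM) had the same order near the floor. The means of Cd2 (0.484, 2.17 and 33.4 RPKM) had it only through non-tumor library 2, at 15.4 RPKM. Non-tumor library 6 read 1.44 RPKM of Cd2 and the remaining ones 0 to 0.138 RPKM, below the heterozygous mean. Dapl1 (4.32, 0.285 and 272 RPKM in the same order of groups) and Vgf (3.19, 0.117 and 218 RPKM) read far higher in tumors than in heterozygous alpha cells. By these levels, such content alone falls short of their rise. Tumor levels above those of heterozygous alpha cells were also read for Irx1 (18.3 and 69.8 RPKM), which was not called in alpha cells. The excess was not tested. For these and the other shared rises a part from such content stays open. Levels of alpha cell and tissue libraries come from separate normalisations. Among 8408 genes tested in both comparisons, 14 rose in knockout alpha cells and 7 fell. Relative to the shift, 11 of those 14 also rose in tumors: Apoa2, Cav1, Cd2, Dapl1, Gc, Peg10, Rec8, selenoprotein P (Sepp1), Serping1, Slc38a5 and Vgf. Chance gives 4.74 (one-sided Fisher's exact p = 0.000791), by a test on centred tissue calls chosen after seeing the data. With both comparisons centred, a setting fixed beforehand, 16 of 20 rises were shared (chance 6.77, Fisher's exact p = 3.04e-05), and with quantile normalization in both 19 of 24 (chance 9.09, Fisher's exact p = 4.40e-05). On the deposited scale, where nearly all genes rose, the overlap was 13 of 14 against 13.5 by chance (Fisher's exact p = 0.912). Of the 7 falls, Cpa1 and Mt1 fell in tumors on the deposited scale (chance 0.0841, Fisher's exact p = 0.00288), but without members of other cell type lists only Mt1 of 6 did (Fisher's exact p = 0.0634). Relative to the shift Ier2 joined them, for 3 against 2.03 by chance (Fisher's exact p = 0.330). In tumors Mt1 read 10.6 ± 7.72 RPKM against 100.1 ± 35.2 RPKM in non-tumor tissue (log2 fold change −3.32, −4.86 relative to the shift). Mt1 was lowest in tumor 5 (2.44 RPKM, acinar list at 1.1% of values) and highest in tumor 7 (23.5 RPKM, 28.0%). Between them the tumors did not follow the acinar share exactly. Mt1 is not on the acinar list, so leaving out list members does not account for loss of acinar tissue. Such loss as the source of the fall of Mt1 in tumors was not tested and stays open. Rec8 rose in tumors by 3.71 (2.18), Cd2 by 4.35 (2.81) and Apoa2 by 4.99 (3.45). Called in opposite directions were 3 genes on the deposited scale (Ctxn2, Jun and Egr1; 12 without heterozygous library 3) and 1 on centred values (Ctxn2). Across genes, which are not independent replicates, fold changes of the comparisons had Pearson r = 0.125 and Spearman rho = 0.047, with r from 0.073 and rho from 0.013 (both without heterozygous library 3) to 0.214 and 0.080 (both without heterozygous library 1). With 1 alpha cell library left out, the number shared on the deposited scale ran from 4 without heterozygous library 2 to 42 without heterozygous library 1, when acinar genes joined the falls.

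**Figure D5:**
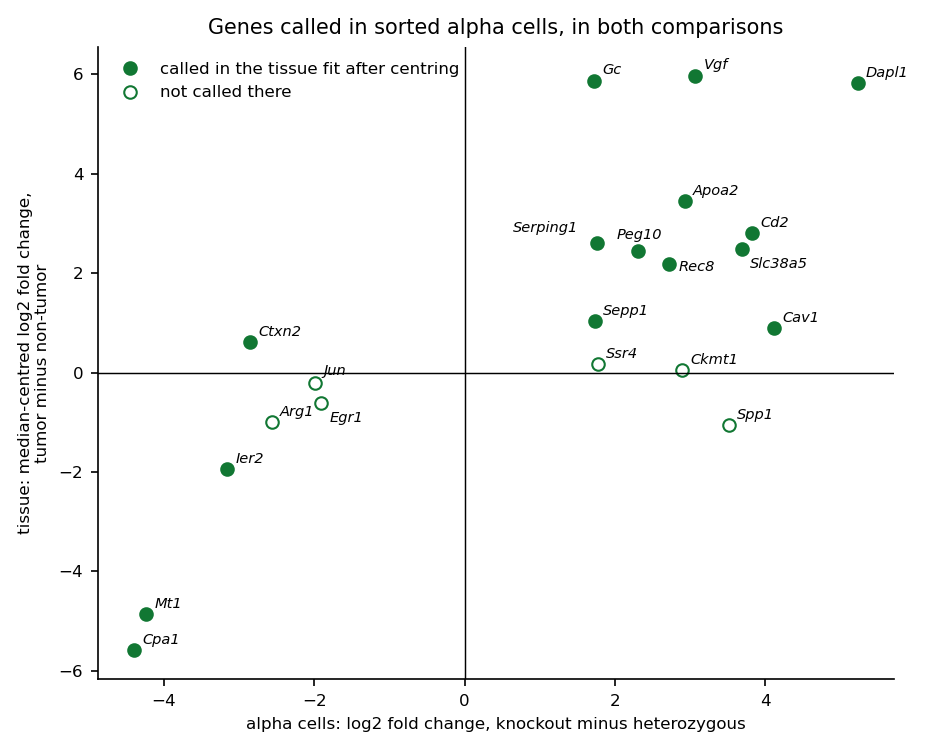
Genes called in knockout alpha cells and tested in both comparisons, with the alpha cell log2 fold change (horizontal) and the tumor log2 fold change relative to the shift (vertical). Filled points were also called in tumors after centring; Dapl1 (5.23 and 5.82) and Slc38a5 (3.69 and 2.49) rose in both, and Cpa1 (−4.40 and −5.59) and Mt1 (−4.23 and −4.86) fell in both.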

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

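Tests of the immediate early list, of depth, of voom on recovered reads, of the 50 highest genes and of non-tumor library 2 were chosen only after the results were seen; tests of regrouped libraries and of the 10 highest genes were fixed beforehand.

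Immediate early genes lay lower in knockout than in heterozygous alpha cells, with a median log2 fold change of −1.54. Acinar carry-over would give a median of 0.013% of the difference over the 19 members that were lower, which argues against it. The median was −1.42 with the set of libraries, more or fewer genes detected, as a covariate and −1.58 without the female heterozygous library 3, which argues against both as the whole cause. A difference in the time or handling between dissociation and sorting was not tested and stays open, as does the genotype. The list may therefore reflect either handling or genotype.

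Most genes rose in tumors on the deposited scale, by a median of 1.46. After scaling each library to its sum outside 29 genes, those among the 10 highest of any library, the median was 1.51, which argues against those few genes alone. Outside 113 genes, those among the 50 highest of any library, the median was 0.27. That number of genes was tried once the first result was known. Of the values, 5.90% in non-tumor tissue and 29.9% in tumors lay outside these genes. A true rise of most genes would also give a median near 0 under such scaling, so it does not tell the causes apart. Of the non-tumor libraries, 5 had at least as many reads as the shallowest tumor, and the highest of their median log2 levels was 1.48 against a lowest tumor value of 2.74, which argues against depth. A candidate explanation is that acinar enzyme transcripts, 72.1 to 81.2% of non-tumor values, leave less room for all other genes. The authors' factor per library also enters: limma voom on the recovered reads gave a median of 2.68 with library totals and 0.09 with size factors, so the size of the shift depends on the scaling. A true rise in RNA per cell was not tested.

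Non-tumor library 2 stood apart from the other 7 in 10 of the 23 values below. Its median excess in 5 lists of other cell types lay 2.39 log2 units apart from highest to lowest, which argues against a lower acinar share alone. The immune list lay 1.52 above the highest of the other 4, with 10 of 11 immune genes above all 7 other libraries. Immune cells in the dissected piece are a candidate source, though 22 of 23 proliferation genes also lay above all 7 others. A biological difference of that animal, such as inflammation, was not tested.

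A library far from the others of its group was found for 23 of 216 values, by the gap to the nearest library over the range of log2(RPKM + 1); chance alone gives about 1 in 20 groups. In knockout alpha cells the gap was 1 for Gcgr in library 4 (highest, with the other 4 at 0), 0.778 for Mir546 and 0.738 for Arg1 in library 2 (both lowest), 0.761 for Ier2 and 0.806 for H2-K1 in library 1 (both highest), and 0.806 for Cela2a in library 3 (highest). In library 5 it was 0.721 for Scg3 (lowest) and 0.743 for Rps27l (highest). Among tumors it was 0.620 for Vgf in tumor 7 and 0.645 for Dapl1 in tumor 1, both lowest. Non-tumor library 2 was highest for Mki67 (0.637), Dapl1 (0.537), Ccne1 (0.611), Fev (1), Ffar4 (0.744), H2-K1 (0.575), Tat (0.669), Rpl7 (0.651) and Cd2 (0.681), and lowest for Mt1 (0.606). Non-tumor library 3 was highest for Gc (0.540) and Gpr119 (0.628), and non-tumor library 1 lowest for Plvap (0.567).

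For the alpha cell comparison, 1 of the 56 splits of the 8 libraries called as many genes as the real one, the real split itself with 28 genes; the highest of the others called 0 (limma). For the tissue comparison 1 of 100 splits drawn did so, the real one with 9647 genes. The highest of the others called 9062 and exchanged tumor 7 with non-tumor library 2, so it kept most of the real grouping. For the alpha cells this argues against a chance division, at 1 of 56, the lowest share that the test can reach. The tissue test could hardly come out otherwise, since tumors of alpha cells were set against mostly acinar tissue, and nothing is concluded from it.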

How the results depend on the processing

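Tests chosen only after the data were seen were those restricted to or adjusted for libraries with more or fewer genes detected, voom on recovered reads, lists on centred values, and the overlap with centred tissue calls alone; the other settings were planned. The cause of each change below was not tested, except where fewer libraries or genes entered.

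The 28 genes of the alpha cell comparison (17 up, 11 down) became 46 with quantile normalization and 90 with array weights. With the acinar covariate they became 48, of which 8 were among the 28. Pseudocounts of 0.1 and 0.01 gave 15 (14 up, 1 down) and 14 (13 up, 1 down), so most of the 11 falls lost their call. With no filter limma called 0 of 19527 genes (1443 at unadjusted p under 0.05). The 4 libraries with fewer genes detected gave 1. The 4 with more gave 2, but hold a single heterozygous library, so no call is read from them. Leaving out a library gave 7 (without heterozygous 2) to 58 (without heterozygous 1), with 57 without heterozygous 3, 18 without knockout 3 and 16 without knockout 5. A sex covariate was not run because the only female library is heterozygous. The 7 alpha cell lists became 0 with an estimated correlation, 2 with fry, 1 with the acinar covariate, 2 in the libraries with fewer genes detected, and 2 (without heterozygous 2) to 6 without a library, with 4 without knockout 3. Slc38a5 kept its call except with no filter and in the libraries with fewer genes detected, and Dapl1 except with no filter, leaving aside the libraries with more genes detected.

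With a replicate block the alpha cell comparison called 2 genes, Slc38a5 and Dapl1, and 4 lists, and the overlap was 2. Deviations of same-numbered alpha cell libraries correlated at 0.001 to 0.087, and those of tissue at −0.222 to 0.149. These values give little sign of pairing by number, but with so few libraries they cannot exclude a shared batch. Alpha cell libraries 1 and 2 of both groups had 13124 to 13882 genes detected, and those with higher numbers 16123 to 16579. The replicate block called 9601 genes in tissue.

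The 9647 genes of the tissue comparison became 6377 (3335 up, 3042 down) with quantile normalization, 6673 after centring (2927 up, 3746 down), 6294 with voom and size factors (3440 up, 2854 down), 9903 with voom and library totals, and 4087 of 4275 with a mean of at least 5 RPKM. Leaving out a library gave 9577 to 9882. The 17 tissue lists became 4 with an estimated correlation, 10 after centring and 13 to 17 without a library. The 15 shared genes became 24 with quantile normalization in both (19 up, 5 down), 19 with centring in both (16 up, 3 down) and 4 (without heterozygous 2) to 42 (without heterozygous 1). Without members of other cell type lists 14 genes were shared (13 up, 1 down), and the falls no longer passed (Fisher's exact p = 0.0634).

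Directions turned for some tumor genes. For Mki67 and Ccne1, which are low, the pseudocount may enter the turn after centring. After centring, Mki67 read −0.14, Esam −0.21, Plvap −0.12, Ccne1 −0.42, Rpl7 −0.35 and Rpl19 −0.21; with quantile normalization Esam read −0.28, Plvap −0.08, Rpl7 −0.26 and Rpl19 −0.27. With voom and size factors Esam read −0.37, Plvap −0.52, Jund −0.22, Rpl7 −0.76, Rpl19 −0.41, mt-Nd5 −0.22 and mt-Nd6 −0.19. With the acinar covariate Pnlip read 0.11, Ero1lb 0.18 and Cpa1 0.59. Without tumor 3 the insulin genes lost their call (Ins2 −1.78, Ins1 −1.89).

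Fry, which does not compare a list with other genes, put upward these tumor lists that camera put downward: delta, PP and epsilon cells (adjusted p = 7.17e-08), ductal (0.0593), endothelial (0.00267), immune (0.0171), fibroblast and mural (0.00528), proliferation (3.18e-05), amino acid transporters (1.73e-08), ATF4 (0.725), unfolded protein response (2.01e-06), sterol synthesis (1.15e-07), hypoxia and glycolysis (1.28e-07), immediate early (5.83e-05), interferon and antigen presentation (0.000465), amino acid catabolism (0.00392), ribosomal proteins (4.42e-05) and mitochondrially encoded (0.0946). After centring, delta, PP and epsilon (0.326, not called on either scale), immune (0.847), fibroblast (0.940) and interferon (0.793) lists turned upward and the respiratory chain (0.0394) downward; with no filter the unfolded protein response turned upward (0.991).

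Of 59 named alpha cell genes, 43 had the same call status with the acinar covariate, while 13 lost their call and 3 gained a call. After centring 58 of the 59 had the same status. Of 70 named tissue genes, 58 did after centring and at least 68 without any 1 library. The same status includes genes called in neither fit, whose direction may have turned. Depth limits the tissue values least in abundant genes; in alpha cells it is unknown.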

Other observations

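Ppy, Ghrl and Gast in the next paragraph were chosen after their values were seen; tests of Slc38a5 across tumors were fixed beforehand.

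Tumors differed from each other in hormones other than glucagon. Ins2 ran from 5.11 to 4172.5 RPKM, with the highest value in tumor 4, and Sst from 11.2 to 1410.2 RPKM, also highest in tumor 4. Non-tumor libraries reached 5652.8 RPKM of Ins2 and 65.3 RPKM of Sst. Islet cells caught in a dissected piece cannot be told from tumor cells as the source of insulin, and the source of Sst was not tested. Pancreatic polypeptide (Ppy) ran from 88.4 to 3464.5 RPKM and Pyy from 314 to 7669.9 RPKM, both highest in tumor 3, where Ins2 was lowest. Ghrelin (Ghrl) reached 37.8 RPKM in tumor 1 and lay between 0.314 and 2.99 RPKM in the other 6. Gastrin (Gast) was listed at 0 in all 8 non-tumor libraries and read 1.26 to 5.41 RPKM in the 7 tumors. Glucagon varied less, from 136765 to 195228 RPKM. Cpa1 ran from 349.5 to 10383 RPKM and was highest in tumor 7, whose acinar list took 28.0% of its values.

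Slc38a5 ran from 245 RPKM in tumor 3 to 1528 RPKM in tumor 6, and 2 hypotheses were tested over the 7 tumors. Its log2 level went with the mean log2 level of the proliferation list with Pearson r = 0.785 (exact permutation p = 0.0359, Benjamini-Hochberg 0.0718 over 2 relations). Spearman rho was 0.607 (exact permutation p = 0.167), and r was 0.767 without tumors 3 and 6, the farthest from the median. The relation does not pass after adjustment, so more dividing cells in tumors with more Slc38a5 remain a hypothesis. Both levels are on the deposited scale, where the median log2 levels of the tumor libraries ran from 2.74 to 3.09. No relation on centred values was tested, so the scaling of the libraries may enter. With the acinar list r was 0.062 (exact permutation p = 0.892, Benjamini-Hochberg 0.892; rho = 0.214, exact permutation p = 0.662; −0.054 without tumors 3 and 6). With 7 tumors this neither favours nor excludes fewer acinar transcripts as the source of its spread.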
